A study of Homo sapiens with 12 samples.

How the data were processed

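RNA-seq libraries of MV4;11 cells, a human acute leukaemia line, were compared in 2 experiments. In the compound experiment, cells were kept for 4 days with DMSO, MS40, pomalidomide or MS40N1, each compound at 0.5 µM. In the knockdown experiment, cells carrying a doxycycline-inducible hairpin against WDR5 (sh#47) or the empty vector (shEV) were kept for 4 days in 0.5 µg/mL doxycycline. Each of the 6 groups had 2 libraries, 12 in all. Groups and replicate numbers were taken from the sample titles. The labels' protocols name a Qiagen RNeasy extraction and Illumina TruSeq library preparation from total RNA. They do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

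The expression values used here are the estimated counts per gene symbol that the authors deposited, marked raw per the file headers. Not all of them are whole numbers, and they are not normalized. The submitters' processing notes name Salmon 0.14.1, BWA, SAMtools and DESeq2 and the build hg19, with no role or order. The annotation release, the way transcripts were summed to genes and any filter on genes are not given in the sources used here. Estimated counts divide reads among transcripts that share sequence, so values of paralogs, pseudogenes and overlapping or read-through genes carry an uncertainty that the replicate spread may not show. The strand setting is likewise not given, so a gene and an antisense partner may not be separated. Because the deposited tables identify genes by symbol alone, no coordinates are printed. A further 20 symbols of the compound table and 18 of the knockdown table had been turned into dates by spreadsheet software, and none of them is named. The log2 fold changes and adjusted p-values that the authors deposited, under DESeq2 column names per the file headers, were used only for comparison. A further 12 deposited columns of normalized values were not used.

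Depth was 12933220 and 22792692 estimated counts in the DMSO libraries, 24139648 and 20003256 in MS40, 14786184 and 14065603 in pomalidomide, 23848461 and 27706354 in MS40N1, 17745212 and 19377693 in shEV, and 20780688 and 21762702 in sh#47. A floor of 3 counts corresponds to 0.108 to 0.228 CPM (counts scaled to a common library total), depending on the library. A gene with 0 counts in a group is given a bound against 3 counts in each library of that group, and a gene with 1 to 3 counts is given a ratio with its 95% counting interval. Floors and counting intervals cover counting error only.

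Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr, scaled with TMM factors (0.968 to 1.02) and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided. The 4 compound groups shared 1 fit, so that each comparison used the spread of all 8 compound libraries, and the 4 knockdown libraries were fitted separately. The tests covered 15381 of 16074 genes in the compound experiment and 13236 of 14713 in the knockdown, with 12960 in both. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of its comparison. Every adjusted p of a single gene is from this test unless another tool or the dispersion of the knockdown libraries is named. Standard errors were derived from the fold change and its F statistic. Levels are TMM-scaled CPM with the SD over 2 libraries.

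There were 7 comparisons: MS40, pomalidomide and MS40N1 each against DMSO, the compounds against each other, and sh#47 against shEV. In addition, 23 gene lists were fixed before the data were examined. They held the compounds' target genes (reported singly), WDR5 complexes, the cereblon ligase with its neosubstrates, the MLL-rearranged leukaemia programme, MYC targets, cytosolic ribosomal proteins, interferon-stimulated genes, MHC class I and class II presentation, monocyte and macrophage maturation, immature myeloid granule genes, S phase, G2/M phase, p53 targets, the ATF4 stress response, cholesterol synthesis, NF-kB inflammatory genes, the mitochondrial genome, and markers of B lymphoid, T and NK, erythroid, megakaryocytic and epithelial or fibroblast cells. Lists with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the preset inter-gene correlation of 0.01, 20 lists in the compound experiment and 19 in the knockdown, adjusted over lists. The test was repeated with an inter-gene correlation estimated from the data. That version refers its statistic to the few residual degrees of freedom of the fit, so it has little power with these libraries. A call lost with it does not by itself show that the members of a list move together. Counts of called members are also given adjusted over the list alone.

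The genes named were chosen by a rule fixed before the data were examined. In the 4 comparisons with a control, these were WDR5, IKZF1, IKZF3, HOXA9, MEIS1 and MYC, the 8 largest rises and 8 largest falls among called genes with a mean of at least 50 normalized counts in the higher group and no overlap between the libraries of the groups, and the 3 members of lowest p of each called list. In the 3 comparisons between compounds they were WDR5, IKZF1, IKZF3 and the 5 largest differences each way. Clone, antisense, microRNA, snoRNA and pseudogene symbols were left out, a filter that the non-coding RNase_MRP passed. A few genes that the rule takes are not reported here.

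Replicates were compared before use. Chi-square per gene between the libraries of a group was 1.73 in DMSO, 2.35 in MS40, 1.67 in pomalidomide and 1.64 in MS40N1, against 10.4 in shEV and 27.1 in sh#47, and no 2 libraries held identical values. The biological coefficient of variation was 2.09% in the compound libraries and 11.5% in the knockdown libraries. The headers of 4 compound libraries carry the same sample number, but no sequencing run is given for any library, so no batch term was fitted.

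The procedure was tested on simulated counts with 200 genes changed by known folds, 50 per fold. The changed genes were drawn from those with an expected count of at least 50 in the smallest library. The shares below therefore do not cover genes of lower count. For MS40 against DMSO (15089 genes), 66% of genes changed by 1.25-fold, 94% of those changed by 1.5-fold and 100% of those changed by 2-fold were called, with 18 false calls among 198. For pomalidomide against DMSO (15101 genes) the shares were 72%, 84% and 98%, with 12 false among 189, and for MS40N1 against DMSO (15088 genes) 80%, 98% and 100%, with 17 false among 206. For sh#47 against shEV (13028 genes) they were 2%, 44% and 86%, with 19 false among 135, and 100% at 4-fold. False calls thus ran above the nominal 5% in each simulation.

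Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter, a filter of at least 50 counts in 2 libraries, the replicate number as a block, each library left out in turn, only the 2 groups compared in the fit, an added threshold of 2-fold, and the estimated inter-gene correlation. The dispersion of the knockdown libraries applied to the compound libraries was added after the data were seen. It used the likelihood ratio test of edgeR with a trended dispersion in place of the F test. Each gene's own spread did not enter, so calls changed by it may reflect the change of test as well as the wider spread. A reference annotation of another build (GRCh38) served only for transcript length and GC content.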

Results

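RNA was sequenced from MV4;11 cells, a human acute leukaemia line with a rearrangement of the MLL (KMT2A) gene. The submitters describe MS40 as a degrader of WDR5, a scaffold of the MLL/SET1 histone methyltransferases, and of Ikaros (IKZF1), a transcription factor. Pomalidomide binds the E3 ligase receptor cereblon and directs IKZF1 and IKZF3 to degradation. MS40N1 is described as an analog of MS40 whose E3 function is dead. DMSO, MS40, pomalidomide and MS40N1 were compared at a matched dose and time, and a WDR5 hairpin (sh#47) was compared with its empty vector (shEV). Each group had 2 libraries with library totals of 12933220 to 27706354 estimated counts.

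WDR5 mRNA was at 139 and 134 CPM in the shEV libraries and at 30.8 and 30 CPM in the sh#47 libraries. It was 4.48-fold lower after knockdown (log2 -2.16 ± 0.11 SE, adjusted p = 1.78e-05). In the compound experiment WDR5 mRNA was at 130 and 126 CPM in DMSO, 130 and 128 in MS40, 139 and 137 in pomalidomide, and 121 and 126 in MS40N1. MS40 differed from DMSO by log2 0.01, with a 95% interval of -0.06 to 0.09 (adjusted p = 0.796). IKZF1 mRNA rose from 302 ± 7.4 CPM in DMSO to 447 ± 0.405 in MS40 (log2 0.56 ± 0.03 SE, adjusted p = 8.24e-10) and to 503 ± 6.09 in pomalidomide (0.73 ± 0.03, 3.49e-11). In MS40N1 it was at 306 ± 0.54 CPM (0.02, interval -0.04 to 0.07, 0.895). IKZF1 was at 253 ± 8.32 CPM in shEV and 223 ± 1.66 in sh#47 (-0.18, adjusted p = 0.266). IKZF3, the gene of Aiolos, stayed at 0.254 to 0.825 CPM in the compound groups, with no called difference (pomalidomide against DMSO 1.47, adjusted p = 0.0625, but 0.0201 without DMSO replicate 2, in a range of 0.0201 to 0.259), and was below the filter in the knockdown. WDR5 mRNA also passed the test in pomalidomide (0.11, 0.0242), a call that was lost without DMSO replicate 2 (0.184), pomalidomide replicate 1 (0.113) or pomalidomide replicate 2 (0.0617) and with DESeq2 (0.16). Its adjusted p ranged from 0.016 to 0.748 over the alternatives, and these are mRNA levels, since no protein was measured here.

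**Figure D1:**
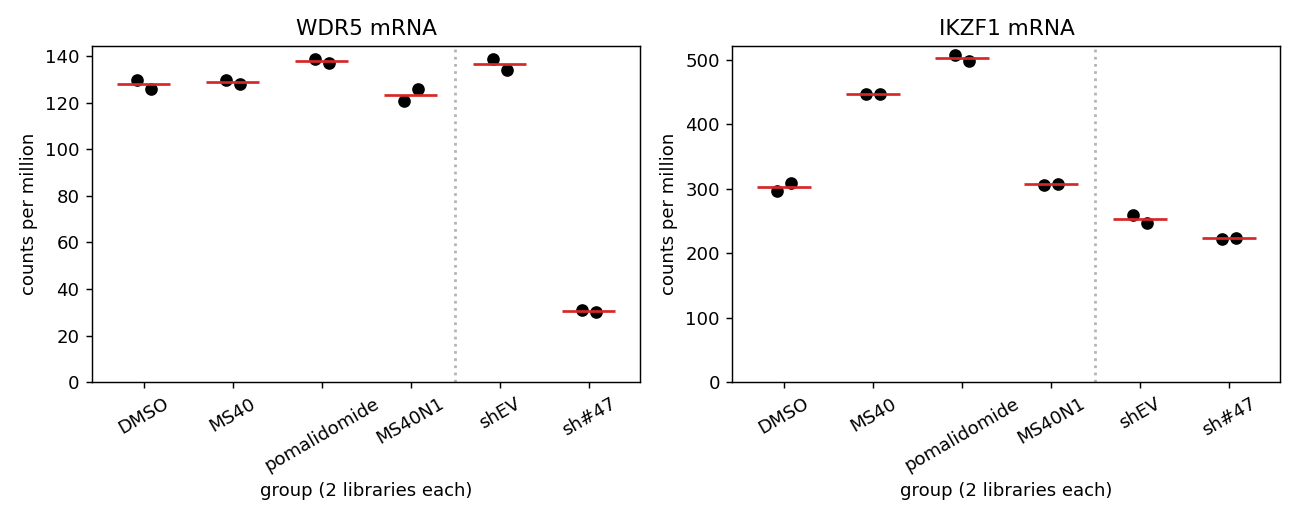
WDR5 mRNA (left) and IKZF1 mRNA (right) in CPM (y axis, from 0) in each library (points) of the 6 groups (x axis), with the group mean as a line. The dotted line separates the compound and knockdown experiments. Both sh#47 libraries lie near 30 CPM for WDR5, and IKZF1 lies higher in both MS40 and both pomalidomide libraries than in DMSO.

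MS40 against DMSO asked what the degrader does to the transcriptome. The largest rise was that of SPARC. This secreted matricellular glycoprotein went from 0.108 ± 0.153 CPM, 5 counts over the DMSO libraries, to 35 ± 0.293 CPM (243-fold, log2 7.93 ± 0.22 SE, adjusted p = 2.8e-12). CD209, the lectin DC-SIGN of dendritic cells and macrophages, rose 36.6-fold to 81.9 ± 0.747 CPM. SIGLEC1, a sialic acid-binding lectin of macrophages, rose 28.8-fold, and SERPINB2, a plasminogen activator inhibitor of monocytes, rose 16.7-fold. At lower levels, SIGLEC11 rose 32.3-fold, ELFN2 23.2-fold, FARP1 17.5-fold and CEACAM6 15-fold. A large fall was that of IGLL1, a component of the pre-B cell receptor's surrogate light chain, from 23.6 ± 0.0788 to 0.271 ± 0.0356 CPM (85.8-fold lower, -6.42 ± 0.15, 6.25e-13). KCNE1, a potassium channel subunit, was 8.79-fold lower, FOXA1, a pioneer transcription factor, 7.85-fold, C11orf95 7.65-fold, IGSF10 6.62-fold and HSH2D, a haematopoietic adaptor, 6.48-fold. The read-through genes INO80B-WBP1 (0 counts in MS40, at least 21.1-fold lower) and MSH5-SAPCD1 (5.76-fold lower) share sequence with their neighbours. The INO80B-WBP1 call (adjusted p = 0.021) was lost without DMSO replicate 2 (0.107), MS40 replicate 1 (0.0855) or MS40 replicate 2 (0.0644), and with DESeq2 (0.0588), in a range of 7.55e-17 to 0.107 over the alternatives.

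Among the gene lists, monocyte and macrophage maturation genes rose with MS40. Of 32 measured members, 23 rose and 2 fell (23 and 4 adjusted over the list alone), with a median log2 change of 0.50 and a camera adjusted p of 2.05e-09 (0.0356 with an estimated correlation). LYZ, lysozyme, rose from 774 ± 5.75 to 2000 ± 44.3 CPM (1.37 ± 0.02), CSF1R, the receptor of macrophage colony-stimulating factor, rose by 0.94 ± 0.03 and FGL2 by 0.82 ± 0.03. Cell cycle genes rose by small amounts. In the S phase list 24 of 44 rose and 4 fell (26 and 5 adjusted over the list alone, median 0.14, camera adjusted p = 8.19e-05, and 0.0468 with an estimated correlation), including the replication genes MCM2 (0.27 ± 0.03) and MCM10 (0.33 ± 0.04) and the thymidine kinase TK1 (0.36 ± 0.04). In the G2/M list 27 of 46 rose and 1 fell (30 and 1 adjusted over the list alone, median 0.14, 4.38e-06, and 0.0391 with an estimated correlation), including MKI67 (0.21 ± 0.03), TPX2 (0.22 ± 0.03) and ANLN (0.23 ± 0.04). All of these cell cycle genes lost their call with the wider dispersion of the knockdown libraries, at adjusted p from 0.0963 for TK1 to 0.534 for MKI67, the highest of each gene's alternatives, while the lowest ranged between 1.63e-11 for MCM2 and 9.37e-05 for ANLN.

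MHC class II genes had 8 of 13 members higher and 1 lower (9 and 2 adjusted over the list alone, median 0.93, camera adjusted p = 8.19e-05, but adjusted p = 0.0533 with an estimated correlation). HLA-DRA rose by 1.22 ± 0.06, HLA-DMA by 1.33 ± 0.10 and HLA-DRB1 by 0.87 ± 0.07, with the caution that estimated counts may split reads among HLA paralogs. Interferon-stimulated genes had 14 of 44 higher and 3 lower (16 and 4 adjusted over the list alone, median 0.20, 0.00207, and adjusted p = 0.0623 with an estimated correlation). LGALS3BP, a secreted galectin-binding protein, rose 8.02-fold, IFITM3, a restriction factor of viral entry, 3.56-fold and IFI6 2.02-fold. Transcripts of the mitochondrial genome were lower for 13 of 13 genes (13 adjusted over the list alone, median -0.45, 2.59e-08, and adjusted p = 0.273 with an estimated correlation). MT-ATP6 fell from 1440 ± 46.1 to 991 ± 4.92 CPM, MT-ND5 by 0.46 and MT-CYB by 0.58 on the log2 scale. The share of counts from the mitochondrial genome was 2.31% and 2.41% in DMSO and 1.84% and 1.89% in MS40. Estimated counts of ribosomal protein genes share sequence with many pseudogenes. These genes were split, 23 higher and 44 lower of 79 (26 and 47 adjusted over the list alone, median -0.17, 0.000666, and adjusted p = 0.505 with an estimated correlation), and RPL7A (-0.39 ± 0.02), RPL29 (-0.50 ± 0.03) and RPL3 (-0.28 ± 0.02) fell. The list test kept its direction under DESeq2 size factors. With the wider dispersion of the knockdown libraries, the calls of RPL7A (0.0877) and RPL3 (0.376) were lost, in ranges of 3.31e-64 to 0.0877 and 4.19e-56 to 0.376 over the alternatives.

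The p53 target list was slightly lower in MS40, with 7 of 28 lower and 1 higher (8 and 1 adjusted over the list alone, median -0.15, camera adjusted p = 0.0296, and adjusted p = 0.141 with an estimated correlation). The death receptor gene TNFRSF10B (-0.23 ± 0.04), ZMAT3 (-0.40 ± 0.09) and the kinase gene PLK2 (-1.07 ± 0.27) fell. The ZMAT3 call was lost with DESeq2 (0.11, range 0.00327 to 0.349), and that of TNFRSF10B with the knockdown dispersion (0.502, range 0.000449 to 0.502). The list call was lost without DMSO replicate 2 (0.0656) or MS40 replicate 2 (0.0508), in a range of 0.0221 to 0.141 over the alternatives. The PLK2 call (adjusted p = 0.0072) was lost without DMSO replicate 1 (0.0578) or MS40 replicate 1 (0.0715) and with DESeq2 (0.0688), and ranged from 0.0037 to 0.156. Cholesterol synthesis had 7 of 23 lower and 1 higher, with the same numbers adjusted over the list alone (median -0.09, 0.0263, and adjusted p = 0.141 with an estimated correlation). INSIG1, a brake on sterol synthesis, fell by 0.52, LSS, lanosterol synthase, fell by 0.43 on the log2 scale, and PMVK, phosphomevalonate kinase, rose by 0.29. The calls of LSS (0.149, range 0.000246 to 0.149) and PMVK (0.384, range 0.000306 to 0.384) were lost with the knockdown dispersion. MYC, the proto-oncogene, was lower by a small amount (-0.14 ± 0.03, 0.000731), a call lost with that dispersion (0.793, range 6.59e-05 to 0.793). MEIS1, a homeobox cofactor of MLL leukaemia, was higher (0.16 ± 0.04, 0.0122), a call lost without DMSO replicate 1 (0.0651) or MS40 replicate 1 (0.0836) and with DESeq2 (0.196), in a range of 0.00838 to 0.741. HOXA9, its partner, did not pass (-0.06, interval -0.17 to 0.06, 0.463).

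The other lists did not pass in MS40. WDR5 complexes had 2 higher and 5 lower of 18 (the same adjusted over the list alone; camera adjusted p = 0.177), the cereblon ligase and its neosubstrates 5 and 3 of 20 (6 and 4; 0.215), the MLL-rearranged programme 3 and 9 of 21 (4 and 9; 0.162), MYC targets 12 and 4 of 51 (12 and 6; 0.363), and MHC class I presentation 5 and 3 of 17 (8 and 3; 0.363). Immature myeloid granule genes had 4 higher and 6 lower of 19 (6 and 7; 0.616), ATF4 stress genes 7 and 9 of 31 (8 and 10; 0.736) and NF-kB inflammatory genes 2 and 6 of 22 (2 and 6; 0.159). Markers of other cell types were few. B lymphoid markers had 7 measured members (1 higher, 3 lower; 0.362), megakaryocytic markers 10 (3 and 2; 0.363) and epithelial or fibroblast markers 5 (1 and 1; 0.765). Only 4 of 21 T and NK markers and 4 of 22 erythroid markers were measured, so these were not tested, and their highest levels were those of NKG7 (60.3 CPM) and the transferrin receptor TFRC (267 CPM), named after their values were seen. In all, 4797 of 15381 genes were called in MS40, 2529 higher and 2268 lower, of which 395 and 237 changed at least 2-fold. The DESeq2 Wald test called 2508. The knockdown dispersion gave 1012 calls, 985 of them among the 4797. The authors' deposited table holds 2414 at an adjusted p under 0.05, of which 2411 were also called here in the same direction.

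Pomalidomide against DMSO asked what the cereblon ligand does alone. SPARC rose 1240-fold, to 179 ± 1.45 CPM (log2 10.28 ± 0.14 SE, adjusted p = 9.45e-16), and CD209 68.4-fold, to 153 ± 0.833 CPM. Several of the largest rises were of genes nearly silent in DMSO. NNMT, nicotinamide N-methyltransferase, and GPX8, a peroxidase of the endoplasmic reticulum, had 0 counts in DMSO and were at least 16.4-fold and at least 15.9-fold higher. EFNB3, an ephrin ligand, had 1 count in DMSO (ratio interval 32.1 to 7240). VSIG4, a complement receptor of macrophages (43.4 to 1320), RNASE1, a secreted ribonuclease (33.5 to 1020), and VTN, vitronectin (23.1 to 710), had 2 counts each. IGLL1 fell to 0.143 ± 0.00514 CPM, 158-fold lower. FOXA1 was 18.2-fold lower, SLC13A3, a dicarboxylate transporter, 13-fold, GAPT 8.14-fold, C11orf95 8.04-fold, PEG3 7.8-fold, CELSR2 7.33-fold and ITGA3, an integrin subunit, 7.02-fold.

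Antigen presentation and monocyte genes rose in pomalidomide. Of 13 MHC class II genes, 12 rose and 1 fell, with the same numbers adjusted over the list alone (median 1.77, camera adjusted p = 7.13e-07, and 0.0491 with an estimated correlation). HLA-DRA rose 4.5-fold to 78.9 ± 0.396 CPM, HLA-DRB1 2.82-fold and HLA-DMA 3.53-fold. Monocyte and macrophage maturation genes had 23 of 32 higher and 2 lower (25 and 3 adjusted over the list alone, median 0.75, 6.29e-10, and 0.0341 with an estimated correlation). LYZ rose to 2690 ± 23.5 CPM (1.80 ± 0.02), S100A9, a subunit of calprotectin, rose 33.4-fold to 25 ± 0.065 CPM and CSF1R 2.19-fold. MHC class I presentation had 9 of 17 higher and 0 lower (12 and 2 adjusted over the list alone, median 0.19, 0.00473, but adjusted p = 0.184 with an estimated correlation), with HLA-B at 0.39 ± 0.02 and B2M at 0.33 ± 0.02. Both calls were lost with the dispersion of the knockdown libraries (0.0547, range 5.12e-46 to 0.0547, and 0.129, range 1.1e-38 to 0.129). Interferon-stimulated genes had 16 of 44 higher and 4 lower (17 and 4 adjusted over the list alone, median 0.24, 0.000995, and adjusted p = 0.0627 with an estimated correlation), led by LGALS3BP (13.4-fold), IFITM3 (7.18-fold) and IFI6 (2.33-fold).

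Cytosolic ribosomal protein genes rose in pomalidomide, 77 of 79 with 0 lower (77 adjusted over the list alone, median 0.20, camera adjusted p = 3.39e-16, but adjusted p = 0.206 with an estimated correlation), with the same direction of the list test under DESeq2 size factors. RPSA rose by 0.37 ± 0.02, RPL31 by 0.38 ± 0.02 and RPLP0 by 0.26 ± 0.02. These genes took 15.1% and 15.2% of counts in pomalidomide, 13.7% and 13.9% in DMSO, and 12.8% in each MS40 library. Genes of the MLL-rearranged programme had 12 of 21 lower and 1 higher (13 and 1 adjusted over the list alone, median -0.13, 0.00364, and adjusted p = 0.0839 with an estimated correlation). BCL2, an inhibitor of apoptosis, fell from 157 ± 7.6 to 57.8 ± 1.72 CPM (-1.43 ± 0.04), and the receptor tyrosine kinase FLT3 (-0.42 ± 0.02) and the cell cycle kinase CDK6 (-0.34 ± 0.03) fell by less. MYC was lower (-0.29 ± 0.03, 7.58e-07), while HOXA9 (-0.10, 0.179) and MEIS1 (0.04, 0.533) did not pass. S phase genes had 21 of 44 higher and 3 lower (21 and 4 adjusted over the list alone, median 0.12, 0.00224, and adjusted p = 0.0627 with an estimated correlation), with TK1 (0.43 ± 0.04) and RRM1 (0.32 ± 0.03) higher and UHRF1, which maintains DNA methylation, lower (-0.40 ± 0.05). G2/M genes had 18 of 46 higher and 1 lower, with the same numbers adjusted over the list alone (median 0.10, 0.0023, and adjusted p = 0.0627 with an estimated correlation), among them CDC25B (0.40 ± 0.04), NUSAP1 (0.24 ± 0.03) and CDC20 (0.36 ± 0.05). Transcripts of the mitochondrial genome fell, 12 of 13 (12 adjusted over the list alone, median -0.42, 4.02e-06, and adjusted p = 0.265 with an estimated correlation), including MT-ATP6 (-0.47), MT-ND5 (-0.49) and MT-CO1 (-0.40). Their share of counts was 1.8% and 1.88%. The p53 list (1 higher, 8 lower of 28; median -0.15, 0.0647, but 0.0359 with the stricter filter, range 0.0359 to 0.184), cholesterol synthesis (2 and 7 of 23; 0.0941), MYC targets (4 and 12 of 51; 0.083) and WDR5 complexes (3 and 6 of 18; 0.156) did not pass. In all 5937 genes were called, 3168 higher and 2769 lower, of which 661 and 393 changed at least 2-fold. With the wider dispersion of the knockdown libraries MYC, CDK6, RPSA, RPL31, RPLP0, RRM1, NUSAP1, CDC20 and MT-CO1 lost their calls, at adjusted p from 0.061 for MT-CO1 to 0.316 for NUSAP1, the highest of each gene's alternatives, while the lowest ranged between 1.16e-76 for RPSA and 1.37e-05 for NUSAP1. That dispersion gave 1740 called genes, 1702 of them among the 5937. The DESeq2 Wald test called 3577, and the authors' deposited table holds 3449, of which 3443 were also called here in the same direction.

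MS40N1 against DMSO asked what remains when the analog's E3 function is dead. Called differences were few and small. LYZ was higher (0.15 ± 0.02, adjusted p = 0.0224), as was SRGN, the granule proteoglycan serglycin (0.13 ± 0.02, 0.0193). The AP-1 gene FOS (-0.55 ± 0.08, 0.0135), MAPK8IP3 (-0.47 ± 0.08, 0.0392), LENG8 (-0.31 ± 0.04, 0.0135) and the mitochondrial genes MT-ND1 (-0.25 ± 0.03), MT-ATP6 (-0.22 ± 0.02), MT-ND5 (-0.21 ± 0.03) and MT-ND6 (-0.21 ± 0.04) were lower. GOLGA8O (-1.22 ± 0.16, 0.00888), whose golgin paralogs are near-identical, was uneven between the DMSO libraries (10 ± 2.25 CPM). In all 18 of 15381 genes were called, 4 higher and 14 lower, 2 of them at least 2-fold, while 1670 had an unadjusted p under 0.05. For 12643 genes, 82.2%, the 95% interval of the difference from DMSO lay within 2-fold either way. The number of called genes was 6 without DMSO replicate 1, 1 without DMSO replicate 2, 3 without MS40N1 replicate 1 and 0 without MS40N1 replicate 2, so each call named here was lost with at least that library left out. DESeq2 called 104, 78.8% of them higher, against 22.2% of the 18. The authors' deposited table gives an adjusted p for 804 genes and holds 105 under 0.05, 82 of them higher, and 12 of the 105 were also called here in the same direction.

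Small shifts of whole lists passed the preset test in MS40N1, and none passed with an estimated correlation. Ribosomal protein genes had a median of 0.08 with 0 of 79 called, but 66 higher adjusted over the list alone (camera adjusted p = 4.44e-19, and adjusted p = 0.203 with an estimated correlation). RPLP0 (0.09) and RPS14 (0.11) were among the members of lowest p, and both were called by DESeq2 (3.66e-05, range 3.66e-05 to 1, and 0.00033, range 0.00033 to 1). Mitochondrial genome transcripts fell, 6 of 13, or 12 adjusted over the list alone (median -0.19, 8.13e-11, and adjusted p = 0.203 with an estimated correlation), with shares of 2.02% and 2.12%. Cholesterol synthesis had a median of -0.10 (0 called, 4 lower adjusted over the list alone; 3.03e-05, and adjusted p = 0.0716 with an estimated correlation), where SREBF2, LSS and DHCR7 were at -0.13, -0.26 and -0.26. Interferon-stimulated genes had a median of -0.11 (0 called either way; 5.43e-05, and adjusted p = 0.0716 with an estimated correlation), with SAMD9L at -0.32, OAS2 at -0.33 and MX1 at -0.51. MHC class II genes were at 0.15 (0 called, 1 adjusted over the list alone; 0.00113, and adjusted p = 0.092 with an estimated correlation), with IFI30 at 0.18, CD74 at 0.05 and HLA-DQB1 at 0.21. The monocyte list was at 0.05 (1 called, 4 adjusted over the list alone; 0.00167, and adjusted p = 0.092 with an estimated correlation), where CCR2 and AIF1 were at 0.14 and 0.12. WDR5 complexes were at -0.05 (0 called, 4 lower adjusted over the list alone; 0.0151, and adjusted p = 0.157 with an estimated correlation), with HCFC1 at -0.14, KMT2A at -0.13 and SETD1A at -0.15, a call lost without DMSO replicate 2 (0.116, range 0.0105 to 0.157). MYC targets were at 0.03 (0 called either way; 0.0189, and adjusted p = 0.203 with an estimated correlation), with CDK4, FBL and HSPD1 at 0.10, 0.09 and 0.09, a call lost without DMSO replicate 1 (0.0693), DMSO replicate 2 (0.116), MS40N1 replicate 1 (0.0608) or MS40N1 replicate 2 (0.0644, range 0.0214 to 0.203). ATF4 stress genes were at -0.03 (0 called, 2 lower adjusted over the list alone; 0.0486, and adjusted p = 0.246 with an estimated correlation), with SLC7A5, SLC3A2 and DDIT4 at -0.10, -0.11 and -0.10, a call lost without DMSO replicate 2 (0.29), MS40N1 replicate 1 (0.0532) or MS40N1 replicate 2 (0.239, range 0.0331 to 0.29). HOXA9 (-0.05), MEIS1 (0.01) and MYC (-0.02) did not pass. Among lists that did not pass, medians and means differed in sign for B lymphoid (0.16 and -0.08), megakaryocytic (-0.11 and 0.04) and epithelial or fibroblast markers (0.09 and -0.06).

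MS40 and its analog MS40N1 were compared directly, at the same dose and time. SPARC was 160-fold higher in MS40 than in MS40N1 (7.32 ± 0.18), SIGLEC1 36.1-fold, CD209 24.8-fold, SERPINB2 22.9-fold and SIGLEC11 20.8-fold, while IGLL1 was 74.9-fold lower (-6.23 ± 0.15), KCNE1 9.68-fold, FOXA1 8.44-fold, C11orf95 7.31-fold and HSH2D 6.27-fold. IKZF1 mRNA was higher in MS40 (0.54 ± 0.03, adjusted p = 8.08e-10), and WDR5 mRNA differed by 0.06 (interval -0.01 to 0.13, 0.188). Interferon-stimulated genes (20 of 44 higher, 1 lower; 25 and 2 adjusted over the list alone; camera adjusted p = 3.59e-07, and 0.0199 with an estimated correlation), monocyte genes (22 and 3 of 32; 23 and 3; 1.99e-09 and 0.0199), S phase genes (24 and 4 of 44; 26 and 5; 9.74e-05 and 0.0375) and G2/M genes (32 and 1 of 46; 34 and 2; 5.42e-08 and 0.0199) were higher in MS40. MHC class II genes were higher (8 and 2 of 13; 8 and 2; 0.00176, and adjusted p = 0.089 with an estimated correlation). Ribosomal protein genes (5 higher and 50 lower of 79; 8 and 52; 6e-10, and adjusted p = 0.377 with an estimated correlation), mitochondrial genome transcripts (0 and 12 of 13; 0 and 13; 2.58e-06 and 0.377) and the p53 list (1 and 10 of 28; 1 and 11; 0.0194 and 0.133) were lower, the last lost without MS40N1 replicate 2 (0.0517, range 0.00987 to 0.133). In all 4544 genes differed, 2388 higher and 2156 lower in MS40, 612 of them at least 2-fold. Pomalidomide and MS40N1 differed in 5679 genes, 3031 higher and 2648 lower in pomalidomide, 963 of them at least 2-fold. SPARC was 816-fold higher in pomalidomide than in MS40N1, GPX8 at least 24.3-fold, EFNB3 (ratio interval 45.8 to 10300), VSIG4 (61.8 to 1880) and NNMT (26.5 to 6070) had 1 or 2 counts in MS40N1, and IGLL1 was 138-fold, FOXA1 19.6-fold, SLC13A3 10.8-fold, ITGA3 8.71-fold and C11orf95 7.68-fold lower. IKZF1 mRNA was higher in pomalidomide than in MS40N1 by 0.71 ± 0.03 (3.21e-11), and WDR5 mRNA by 0.15 ± 0.03 (0.00236, but 0.643 with the knockdown dispersion, range 0.00116 to 0.643). Genes of MHC class II were higher in pomalidomide than in MS40N1, 10 of 13 with 1 lower, the same adjusted over the list alone (camera adjusted p = 1.84e-06, and 0.0384 with an estimated correlation). Monocyte genes had 23 of 32 higher and 4 lower (25 and 4 adjusted over the list alone, 5.01e-10 and 0.0323), interferon-stimulated genes 23 of 44 and 2 (26 and 2, 8.9e-07 and 0.0323) and G2/M genes 23 of 46 and 1 (24 and 1, 0.000164 and 0.0391). Ribosomal protein genes (70 of 79 higher, 0 lower, adjusted p = 0.327 with an estimated correlation), MHC class I genes (10 and 1 of 17, 0.147) and S phase genes (19 and 3 of 44, 0.066) were higher by the preset test alone. The MLL-rearranged programme (1 higher and 11 lower of 21, adjusted p = 0.102 with an estimated correlation), MYC targets (2 and 20 of 51, 0.116), mitochondrial genome transcripts (0 and 11 of 13, 0.398) and the p53 list (1 and 8 of 28, 0.147) were lower by that test alone. The p53 call (0.0441) was lost without pomalidomide replicate 1 (0.0936), pomalidomide replicate 2 (0.0806) or MS40N1 replicate 2 (0.0907), in a range of 0.0184 to 0.147. DESeq2 called 2225 genes between MS40 and MS40N1 and 3232 between pomalidomide and MS40N1.

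MS40 and pomalidomide were compared directly, to ask whether the degrader and the cereblon ligand differ. GPX8 was 8.9-fold lower in MS40 than in pomalidomide (-3.15 ± 0.45, adjusted p = 0.000756), CLMP, an adhesion molecule, 7.64-fold, RAB13, a small GTPase, 6.3-fold, NNMT 6.18-fold and SLC52A3, a riboflavin transporter, 6.06-fold. Higher in MS40 were GOLGA8A (2.84-fold, again with near-identical paralogs), THBS1, thrombospondin (1.93-fold), AMY2B, an amylase with close paralogs (1.92-fold), HDAC9 (1.82-fold) and RFX8 (1.76-fold). IKZF1 mRNA was lower in MS40 than in pomalidomide (-0.17 ± 0.03, 0.000664, but 1 with the knockdown dispersion, range 2.6e-05 to 1), and WDR5 mRNA differed by -0.10 (interval -0.17 to -0.02, 0.101). Of these, GOLGA8A was lost without pomalidomide replicate 2 (0.0613, range 0.00258 to 0.0676), AMY2B without MS40 replicate 2 (0.104) or pomalidomide replicate 2 (0.223, range 0.0141 to 0.659), RFX8 without MS40 replicate 1 (0.23) or pomalidomide replicate 2 (0.285, range 0.0336 to 0.965) and THBS1 with DESeq2 (0.0526, range 0.00187 to 0.287).

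Ribosomal protein genes were lower in MS40 than in pomalidomide, 68 of 79 with 0 higher (74 adjusted over the list alone, median -0.38, camera adjusted p = 6.53e-41, and adjusted p = 0.0892 with an estimated correlation). MHC class II genes (9 of 13 lower, 1 higher; 11 and 1 adjusted over the list alone, median -0.61, 2.66e-08, and 0.0324 with an estimated correlation) and monocyte genes (15 of 32 lower, 1 higher; 18 and 2; median -0.21, 6.36e-08 and 0.0324) were also lower in MS40. MHC class I genes were lower (8 of 17, 0 higher; 9 and 0; 3.39e-05, and adjusted p = 0.0892 with an estimated correlation), and the MLL-rearranged programme (8 of 21 higher, 0 lower; 11 and 0; 0.000518, and adjusted p = 0.0717 with an estimated correlation) and MYC targets (10 of 51 higher, 0 lower; 15 and 1; 1.5e-05, and adjusted p = 0.0717 with an estimated correlation) were higher. Epithelial or fibroblast markers were lower (2 of 5, 0 higher; 2 adjusted over the list alone; 0.0198, and adjusted p = 0.144 with an estimated correlation), a call lost without MS40 replicate 1 (0.0591) or pomalidomide replicate 1 (0.0818, range 0.00422 to 0.144). NF-kB inflammatory genes did not pass (0 higher, 2 lower of 22, 0.0541), but lay close to the threshold and passed, among other settings, without MS40 replicate 1 (0.0316), without pomalidomide replicate 2 (0.0128) and with no filter (0.0486, range 0.0128 to 0.334). In all 1493 genes differed, 595 higher and 898 lower in MS40. The number was 983 without MS40 replicate 1, 755 without pomalidomide replicate 1 and 700 without pomalidomide replicate 2, and DESeq2 called 594, 26.9% of them higher against 39.9% of the 1493.

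MS40 and pomalidomide shared 3882 called genes in the same direction against DMSO, and 916 with the dispersion of the knockdown libraries. Of the 3882, 2108 were higher, where independent lists would share 521, and 1774 were lower, where they would share 408. Another 72 genes were called in opposite directions, and 44 of them were cytosolic ribosomal protein genes, all lower in MS40 and higher in pomalidomide. Across genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.815 and a covariance of 0.432. Unchanged groups simulated against the same DMSO libraries gave 0.501 and 0.0368, with a median of 0 shared calls in 20 simulations, so the covariance exceeded the simulated one by 0.395. Each simulated group took the observed DMSO mean as its true level, which may understate the part that shared controls add. The 2 DMSO libraries were not split between the comparisons, and part of the excess in shared calls may come from them. With no library in common, MS40 against MS40N1 and pomalidomide against DMSO had a Pearson correlation of 0.646 (simulated -0.00157). Their Spearman correlation was 0.617 and their covariance 0.315. Of the 1054 genes changed at least 2-fold by pomalidomide, 94.1% had the same sign in MS40 against MS40N1. MS40 and MS40N1 shared 14 called genes against DMSO, with a correlation of 0.438 against 0.551 simulated, and a covariance above the simulated one by 0.0802. That covariance was 0.117, near the 0.118 of pomalidomide with MS40N1. A response shared by MS40 and MS40N1 cannot be told apart here from the shared DMSO libraries. The count of 14 fell to 5 without DMSO replicate 1, 1 without DMSO replicate 2 or MS40N1 replicate 1, and 0 without MS40N1 replicate 2.

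**Figure D2:**
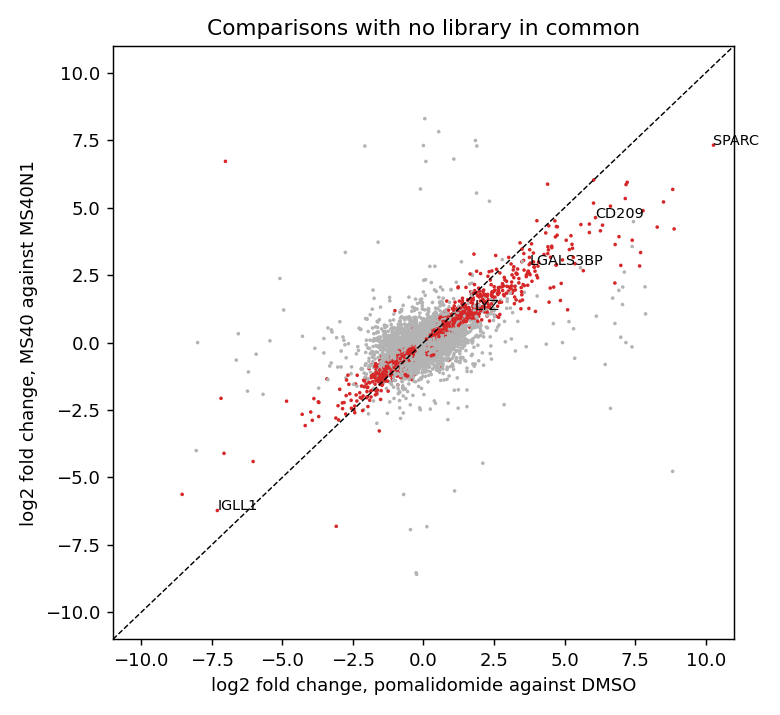
Log2 fold change of pomalidomide against DMSO (x axis) and of MS40 against MS40N1 (y axis), 1 point per gene, for comparisons that share no library. Red points are the genes called in both comparisons, in either direction, and the dashed line marks equal change. SPARC, CD209, LGALS3BP and LYZ lie at the upper right and IGLL1 at the lower left, with a correlation of 0.646 over all genes.

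WDR5 knockdown against the empty vector asked what the WDR5 hairpin does. The control was an empty vector, so an effect of any hairpin is not separated from that of lower WDR5. p53 target genes rose together, 18 of 27 with 1 lower (21 and 1 adjusted over the list alone, median 0.54, camera adjusted p = 2.26e-08, but adjusted p = 0.326 with an estimated correlation). ZMAT3, an RNA-binding p53 target, rose from 14.9 ± 0.486 to 45.2 ± 0.245 CPM (1.60 ± 0.13, adjusted p = 9.57e-05), GADD45A, a stress sensor of growth arrest, by 1.37 ± 0.13, and SESN1, sestrin, by 1.38 ± 0.15. Cholesterol synthesis fell, 16 of 23 with 0 higher (20 adjusted over the list alone, median -0.53, 2.26e-08, and adjusted p = 0.326 with an estimated correlation). LSS went from 154 ± 3.13 to 66.1 ± 5.14 CPM (-1.22 ± 0.11), and MVD, which makes isopentenyl pyrophosphate, was at -1.07 ± 0.11. G2/M genes fell, 15 of 46 with 0 higher (17 adjusted over the list alone, median -0.28, 2.7e-06, and adjusted p = 0.337 with an estimated correlation), including GTSE1 (-1.33 ± 0.13), the mitotic kinase PLK1 (-0.85 ± 0.13) and the phosphatase CDC25B (-0.60 ± 0.11). ATF4 stress genes had 11 of 30 lower and 2 higher (12 and 3 adjusted over the list alone, median -0.19, 0.0174, and adjusted p = 0.326 with an estimated correlation). Among them PHGDH, of serine synthesis, was 3.58-fold lower, from 91.6 ± 0.0736 to 25.6 ± 0.63 CPM, ATF5 2.61-fold and DDIT4, an inhibitor of mTOR signalling, 2.44-fold. That list call was lost without sh#47 replicate 1 (0.17, range 0.00514 to 0.326).

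The largest single rises after knockdown were those of ACTL8 (5.5-fold), DST, the cytoskeletal linker dystonin (5.21-fold), MMP2, a gelatinase (5.17-fold, to 53.4 ± 5.48 CPM), HMOX1, haem oxygenase (5.04-fold), FBXO16 (4.78-fold), SORL1, a sorting receptor (4.51-fold), HLA-DRA (4.31-fold) and STOX2 (4.24-fold). The largest falls included HIC1, a transcriptional repressor (9.46-fold), SLCO4C1 (8.84-fold), DLX2 (8.65-fold), SLC13A3 (7.08-fold), KLF2 (6.89-fold) and SLC6A8, the creatine transporter (6.86-fold). The non-coding RNase_MRP (at least 50.1-fold lower, shEV 7.12 ± 6.64 CPM) and SAP25 (ratio interval 19.2 to 590, shEV 3.25 ± 3.64 CPM) were uneven between the shEV libraries. MHC class II genes rose, 6 of 10 with 0 lower (10 adjusted over the list alone, median 1.14, camera adjusted p = 1.18e-05, and adjusted p = 0.326 with an estimated correlation), with HLA-DMA at 1.11 ± 0.23 and IFI30 at 0.62 ± 0.13, the last lost without shEV replicate 1 (0.0712, range 0.00134 to 0.0712). Monocyte genes had 14 of 30 higher and 1 lower (14 and 2 adjusted over the list alone, median 0.39, 0.000988, and adjusted p = 0.326 with an estimated correlation), with FGL2 at 1.27 ± 0.12, CYBB, the phagocyte oxidase subunit, at 1.85 ± 0.24 and LYZ at 0.84 ± 0.12. Interferon-stimulated genes had 8 of 35 higher and 2 lower (11 and 2 adjusted over the list alone, median 0.22, 0.00528, and adjusted p = 0.326 with an estimated correlation), with TRIM22 at 1.17 ± 0.11, LGALS3BP at 1.31 ± 0.15 and BST2, tetherin, at 0.68 ± 0.11, a list call lost without sh#47 replicate 2 (0.0606, range 0.000957 to 0.326).

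WDR5 complexes had 5 of 18 lower and 0 higher, WDR5 itself among the 5 (5 adjusted over the list alone, median -0.27, camera adjusted p = 0.0158, and adjusted p = 0.385 with an estimated correlation). The methyltransferase gene KMT2B was at -0.65 ± 0.13 and HCFC1, a partner of WDR5, at -0.57 ± 0.15, and both calls were lost without shEV replicate 2 (0.078 and 0.184; ranges 8.51e-05 to 0.078 and 2.5e-05 to 0.184). The list call was lost without shEV replicate 2 (0.0828) or sh#47 replicate 2 (0.0886, range 0.00799 to 0.385). NF-kB inflammatory genes had 6 of 16 lower and 0 higher (6 adjusted over the list alone, median -0.33, 0.0158, and adjusted p = 0.326 with an estimated correlation), with the cytokine TNF at -0.90 ± 0.15, the adhesion molecule ICAM1 at -1.77 ± 0.33 and RELB at -0.70 ± 0.14. Mitochondrial genome transcripts were higher, 7 of 13 with 0 lower (10 adjusted over the list alone, median 0.56, 0.000651, and adjusted p = 0.326 with an estimated correlation), including MT-ND2 at 0.75, MT-ND4 at 0.68 and MT-ND1 at 0.71, the last 2 lost without shEV replicate 2 (0.0714, range 2.67e-07 to 0.0714, and 0.054, range 9.49e-07 to 0.054). Their share of counts was 1.93% and 1.75% in shEV and 3.21% and 2.88% in sh#47, and mitochondrial ribosomal RNA was uneven between the sh#47 libraries, at 1% and 0.571%.

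HOXA9 was at 52.4 ± 0.179 CPM in shEV and 42.1 ± 1.91 in sh#47 (-0.32 ± 0.11), which did not pass (adjusted p = 0.0698) except without sh#47 replicate 1 (0.0299, range 0.0299 to 0.324). In the authors' deposited table, however, HOXA9 is at -0.32 with an adjusted p of 0.0358, under DESeq2 column names. MEIS1 (-0.05, 0.812) and MYC (0.01, 0.967) did not pass here or in that table. The cereblon list had 0 of 18 called, also adjusted over the list alone (camera adjusted p = 0.56), where edgeR gave 2567 calls over all genes. The MLL-rearranged programme had 1 higher and 2 lower of 21 (the same adjusted over the list alone; 0.673), MYC targets 4 and 1 of 51 (2 and 1; 0.26), MHC class I 3 and 0 of 17 (3 and 0; 0.187), S phase 0 and 9 of 44 (0 and 11; 0.148, but 0.0197 without sh#47 replicate 2, in a range of 0.0197 to 0.648), and immature granule genes 4 and 6 of 19 (4 and 7; 0.307). Ribosomal protein genes had 22 higher and 17 lower of 79 (25 and 21; 0.91), with a median of -0.09 and a mean of 0.02, opposite in sign. B lymphoid markers had 0 higher and 2 lower of 6 (0 and 2; 0.307) and megakaryocytic markers 1 and 2 of 8 (1 and 2; 0.153). In all 2567 of 13236 genes were called, 1210 higher and 1357 lower, 192 and 318 of them at least 2-fold. The number was 1548 without shEV replicate 1, 1292 without shEV replicate 2 and 4172 without sh#47 replicate 1. The authors' deposited table holds 2808, of which 2314 were also called here in the same direction.

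**Figure D3:**
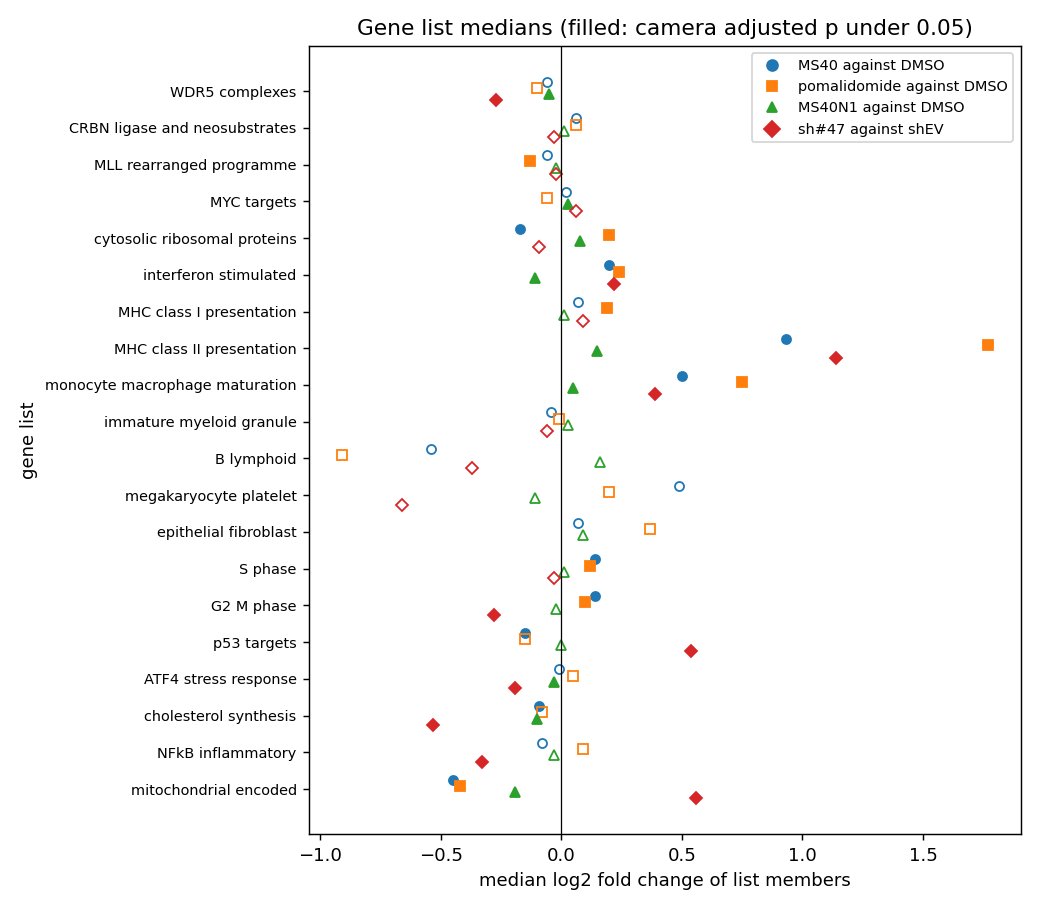
Median log2 fold change (x axis) of the measured members of each gene list (y axis) in MS40, pomalidomide and MS40N1 against DMSO and in sh#47 against shEV. Filled symbols mark a camera adjusted p under 0.05 with the preset correlation. MHC class II medians are 0.93, 1.77, 0.15 and 1.14, and the p53 and cholesterol medians in sh#47 are 0.54 and -0.53.

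MS40 and the WDR5 knockdown, which share no library, had 772 genes called in the same direction among the 12960 tested in both. These were 339 higher, where 213 would be shared by independent lists (odds ratio 1.96, Fisher's exact test p = 3.75e-21), and 433 lower, where 226 would be (odds ratio 2.69, p = 2.2e-49), while 382 were called in opposite directions. Pomalidomide and the knockdown shared 919, with 455 opposite. These were 418 higher against 259 (odds ratio 2.1, Fisher's exact test p = 1.46e-28) and 501 lower against 277 (2.59, p = 1.65e-50). Genes are not independent replicates, so these p-values may be far too small. The correlation of fold changes across genes was 0.139 for MS40 and 0.148 for pomalidomide (Spearman 0.135 and 0.159), and MS40 against pomalidomide had a correlation of -0.07 with the knockdown, with 132 shared calls and 302 opposite. The shared count of MS40 and the knockdown was 486 without shEV replicate 1 and 413 without shEV replicate 2. LGALS3BP, LYZ, FGL2, HLA-DRA and HLA-DMA were among the genes called higher in both MS40 and sh#47, and LSS among those called lower in both. LGALS3BP, LYZ, HLA-DRA and HLA-DMA rose more in pomalidomide than in MS40. Of the 772 genes, 80 were not called in pomalidomide, and 12 of those also differed between MS40 and pomalidomide. ZMAT3 and PLK2, called lower in MS40, are p53 targets, and ZMAT3 was called higher in sh#47.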

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

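No named gene or list that was called, here or under the alternative, changed direction. Values that were not called changed sign in places, among them MYC and MEIS1 in the knockdown and WDR5 in MS40. The balance of the MS40N1 calls also turned: 22.2% were higher by the edgeR test and 78.8% by the DESeq2 Wald test. Only the alternative that gives the compound libraries the dispersion of the knockdown libraries was chosen after the data were seen. It also replaced the F test by a likelihood ratio test without each gene's own spread, and it kept 2 of the 18 MS40N1 calls. With that dispersion the called genes were 1012 in MS40, 1740 in pomalidomide, 32 in MS40N1, 931 between MS40 and MS40N1, 144 between MS40 and pomalidomide and 1585 between pomalidomide and MS40N1, with 916 shared by MS40 and pomalidomide and 203 by MS40 and the knockdown. The DESeq2 Wald test called 2508, 3577, 104, 2225, 594 and 3232 in the same order of comparisons. A threshold of 2-fold left 632, 1054, 2, 612, 118 and 963, and 510 in the knockdown. Fitting only MS40N1 and DMSO gave 56 calls in place of 18. Leaving out each library in turn gave 3335 to 3978 genes in MS40, 4579 to 5076 in pomalidomide, 0 to 6 in MS40N1, 3080 to 3680 between MS40 and MS40N1, 700 to 1127 between MS40 and pomalidomide, 4264 to 4344 between pomalidomide and MS40N1, and 1292 to 4172 in the knockdown. Shared calls then ranged from 2784 to 3321 for MS40 with pomalidomide, 0 to 21 for MS40 with MS40N1 and 413 to 1098 for MS40 with the knockdown. The correlation of MS40 less MS40N1 with pomalidomide less DMSO was 0.448 to 0.552 with a library left out, 0.548 with no filter and 0.814 with the stricter filter, so it rises as genes of low count are removed. That of MS40 with the knockdown was 0.095 to 0.146. WDR5 in the knockdown stayed at -2.19 to -2.15. With an estimated correlation 5 of the 37 list calls in comparisons with a control held, and 10 of the 26 between compounds. The few residual degrees of freedom of that version also end calls, so these losses do not measure how far members move together. The estimated correlations themselves were 0.352 for ribosomal protein genes and 0.809 for mitochondrial genome transcripts in the compound libraries, against the preset 0.01. The preset adjusted p-values of these lists in the compound comparisons may therefore be far too small. Estimates for the other compound lists ran from -0.151 to 0.049. In the knockdown the highest was 0.17, of the cholesterol list. With a library left out 33 to 37 list calls were made in comparisons with a control. Where a library was left out, its partner was taken to vary like the other libraries of the fit; the cause of the other changes was not tested. DESeq2 size factors changed no call of a named gene or list (224 and 139 compared). Of the calls of named genes the DESeq2 test ended 8 and added 7, the knockdown dispersion ended 43, and library omissions, summed over libraries, ended 54 and added 2. No prior count other than 2 was tried for the list tests. Depth limits genes under 0.108 to 0.228 CPM.

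Replicate numbers did not pair the samples: deviations from the group mean of same-numbered libraries had correlations of -0.027 to 0.024. With a replicate block MS40N1 had 32 called genes, and it shared 26 with MS40. The block ended the ATF4 list call in MS40N1 (adjusted p = 0.0816), and brought RPLP0 in MS40N1 (0.0321) and the NF-kB list between MS40 and pomalidomide (0.0462) past the threshold.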

Other observations

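The tests of shared DMSO libraries, of the hairpin's off-target effect, of sampling noise alone and of libraries from 1 culture, the medians over all genes called in the knockdown or those of at least 2-fold, and the list differences between experiments, were chosen after the results were seen. The p53, G2/M and sterol lists moved differently in the compounds and in the knockdown, tested as the difference of the 2 contrasts with limma voom and quality weights over 12960 genes. The p53 list was lower in the MS40 contrast than in the knockdown contrast by a median log2 of -0.60 (camera adjusted p = 1.47e-12, and 0.00329 with an estimated correlation), G2/M genes were higher by 0.46 (1.71e-13 and 0.0193) and cholesterol synthesis by 0.49 (1.51e-10 and 0.0193). Pomalidomide gave -0.66, 0.41 and 0.53 for the same lists (0.00457, 0.0314 and 0.0314 with an estimated correlation). Mitochondrial genome transcripts also differed, at -0.95 for MS40 (1.71e-13, and adjusted p = 0.0659 with an estimated correlation). The knockdown cells carried a vector and had their own controls, so the difference is between experiments as well as between treatments.

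MHC class II genes differed by -0.48 between the MS40 and knockdown contrasts (camera adjusted p = 0.0302, but adjusted p = 0.136 with an estimated correlation). For pomalidomide they did not pass (0.625), with a median difference of 0.25 while the test pointed down. The monocyte list did not pass for MS40 (median difference 0.14, 0.326) and was higher by 0.32 for pomalidomide (0.00771, but adjusted p = 0.154 with an estimated correlation). LYZ was called in each of the 4 comparisons with a control, at 1.37, 1.80, 0.15 and 0.84 for MS40, pomalidomide, MS40N1 and sh#47, the MS40N1 call being lost with any library of its comparison left out (adjusted p 0.104 to 0.337). Genes called in the knockdown had a median change in its direction of 0.034 in MS40N1 over 2546 genes, of which 66.1% had the same sign. Over all 12960 genes tested in both, MS40N1 and the knockdown had a Spearman correlation of 0.174 and a Pearson correlation of 0.087. Only 6 calls were shared and 4 were opposite, and the source of this small trend over all genes was not tested.

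The MS40 response resembled that of pomalidomide. Shared DMSO libraries do not account for this, since comparisons with no library in common still had a correlation of 0.646. Whether loss of WDR5 adds to the MS40 response was asked of the 1172 genes called in the knockdown and not in pomalidomide, whose median change in the knockdown direction was 0 for MS40 against DMSO (95% interval -0.009 to 0.009, 80 called in that direction and 82 in the other) and -0.019 against MS40N1 (-0.031 to -0.011, 76 and 155); both lie under the bound of 0.05 set beforehand, but a set that leaves out called genes and whose members go both ways cannot exclude it. Over all 2546 genes called in the knockdown the median was 0.052 for MS40 against DMSO (772 called in that direction, 382 in the other), 0.021 against MS40N1 (641 and 467) and 0.083 for pomalidomide (919 and 455), and over the 492 of at least 2-fold it was 0.147 (interval 0.096 to 0.192; 149 and 59), 0.104 (0.062 to 0.151; 129 and 70) and 0.179 (0.126 to 0.258; 166 and 66). MS40 against pomalidomide went against the knockdown direction in the 3 sets (-0.013, -0.035 and -0.063, with 20 called in that direction and 55 in the other in the last). Pomalidomide itself moved these genes the knockdown way, and MS40 had the weaker response. For the 1054 genes changed at least 2-fold by pomalidomide, the change in MS40 against MS40N1 was divided by that in pomalidomide. The median ratio was 0.64 (quartiles 0.42 and 0.78), for genes chosen on their pomalidomide change. A weaker shared response alone would also give values against the knockdown direction. This comparison therefore cannot show whether loss of WDR5 adds to the response, and the 2 cannot be told apart. WDR5 protein was not analysed here.

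p53 targets were higher and sterol genes lower after knockdown by the preset correlation alone (adjusted p = 0.326 for each list with an estimated correlation). The estimated correlations were 0.047 and 0.17, and MHC class II genes, at -0.061, had the same camera adjusted p of 0.326. With so few libraries the estimated version has little power, so the lost calls do not decide the matter. A trend with transcript length and GC does not account for the p53 and sterol changes. Across genes the fold change had a Spearman correlation of -0.308 with GC. After a loess on both, the p53 median was 0.70 (interval 0.46 to 0.88, with 26 of 27 genes matched) and the sterol median -0.64. Nor does 1 divergent library, since with any library left out the largest camera adjusted p of the p53 list was 1.75e-06 at the preset correlation, a call that the estimated one ends (adjusted p = 0.326). An off-target effect of the single hairpin, or an effect of any hairpin, cannot be told apart from loss of WDR5, because the design has 1 hairpin and an empty-vector control. A response to WDR5 loss therefore remains a hypothesis.

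Replicates of the compound groups differed far less than those of the knockdown. Repeat sequencing of 1 library with sampling noise alone does not account for this: chi-square per gene over genes with whole-number counts would then be 1, and it was 1.17 in pomalidomide and 1.32 to 1.43 in the other groups, with no 95% interval reaching below 1.05. Few genes carried part of this excess. The means with 5% of genes trimmed at each end were 0.869 in pomalidomide to 0.995 in DMSO. Trimming also brings the value for sampling noise alone below 1, so these means do not show that the other genes hold sampling noise only. Repeat sequencing in runs that themselves differ cannot be told apart from separate libraries, because 1.17 lies between the bounds set beforehand and no sequencing run is given for any library. Separate libraries of 1 culture remain open as well, at a coefficient of variation of 2.09%, and no biological explanation was tested. On either reading the compound p-values may be too small for the treatments. The counts with the knockdown dispersion, such as 1012 for MS40, bear on that, though they come from another test.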
